A study of Mus musculus with 4 samples.

How the data were processed

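Gene expression was measured by RNA sequencing in mouse (C57BL/6) mesenchymal stem cells (MSC, the multipotent stromal cells that give rise to osteoblasts) and in osteoblasts derived from them. There was 1 library of undifferentiated, untreated MSC and there were 3 libraries of cells kept for 13 days in osteogenic medium, which held 100 nM dexamethasone, 10 mM of a phosphoglycerol salt and 50 µM ascorbic acid and was renewed every 3 days. In the osteoblast cultures 25% of the volume was conditioned medium from MCF7, a human oestrogen receptor-positive breast cancer cell line. In 1 library this medium came from control MCF7, and in 2 libraries, which the labels number KD1 and KD2, from MCF7 with SCUBE2 knocked down. SCUBE2 is a secreted protein known for its part in the release of Hedgehog ligands. Total RNA was taken with Trizol and sequenced on libraries made by Illumina protocols, per the labels' protocols. The labels do not say whether KD1 and KD2 are different knockdowns or repeats, nor whether any cultures were separate, so p-values measure only the spread between these samples, which may be technical.

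Per the submitters' processing notes, FastQC 0.11.2, STAR 2.4.2a, RSEM 1.2.29 and edgeR were used with the mouse build mm9, with no role or order given. The annotation release, the strand setting of the counting and the filters are not given in the sources used here. The table for the series carries the words raw counts in its name, but its values are not raw counts. The deposited values are a normalised signal, as reads scaled to a library size that was multiplied by a composition factor. Each column is made of whole multiples of 1 step, and the 4 columns sum to between 97.3% and 104% of the total that unscaled CPM has. The product of that relative sum and the TMM (trimmed mean of M values) factor computed here is 1.01 in all 4 libraries, as for CPM scaled by TMM up to a constant. Whole reads were recovered by dividing by the step. Within a tolerance of 0.1 read, 100% of the non-zero values came out whole in every library. The values are called CPM (scaled read counts) below. The file deposited for the KD2 sample alone has the column name of the KD1 library and its values equal those of KD1 for all 50600 genes, so KD2 was taken from the series table, whose column carries the identifier of the KD2 sample. The KD1 and KD2 columns of that table differed by more than counting noise (mean chi-square of 40.5 per gene over 13752 genes, where counting alone gives 1), and were kept as 2 samples. By the same measure KD2 lay nearer to the control library (20.9) than to KD1, and KD1 lay further from control (73.9). KD1 and KD2 were thus grouped by their labels and not by similarity.

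Of the 50600 gene identifiers, 50376 (99.6%) were found in the GENCODE M21 annotation, which is on another build (GRCm38) and was used for this comparison alone. Whether the reads were in fact counted on the stated build mm9 was not tested and is uncertain. Gene symbols were taken from the deposited table, and no coordinates are given because no annotation of the stated build was used here.

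The test fixed before the data were examined was edgeR's quasi-likelihood test on counts. Since the deposited values are not counts, the test reported is limma (version 3.58.1, R 4.3.3) on log2(CPM + 1), with a mean-variance trend and robust moderation, 3 groups (MSC, control medium, knockdown medium), no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on this log2(CPM + 1) scale, which understates those of low genes. Genes were kept by edgeR's filterByExpr on the recovered reads (a minimum of 10 reads scaled to library size in at least 1 library), which left 14918. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. The fit has 1 residual degree of freedom, KD1 against KD2. The single MSC library and the single control library are assumed to vary as that pair does, and neither has a replicate check of its own. Errors written SE are limma's moderated standard errors. Group means are given with the SD of 2 libraries. Single-library values carry no error. Ratios of a gene with no read in a library use 3 reads of that library as the floor, and the 95% intervals given for 1 to 3 reads are exact binomial (Clopper-Pearson); both cover counting error only, since reads without molecular identifiers are not independent molecules. Depth was 25074727 recovered reads for MSC, 24501129 for control medium, 21785360 for KD1 and 20782984 for KD2.

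The genes named were chosen by rules fixed before the data were examined. The first rule took, for each comparison, the 10 genes with the largest fold change in each direction among those past the threshold with a mean log2(CPM + 1) of at least 2 and, for knockdown medium, both libraries on the same side of control. Where fewer passed, the places were filled by size, ranked by the smaller of the 2 knockdown libraries' differences from control, and such genes are given as values only. The second took up to 4 members past the threshold from each of 30 gene lists, or 2 members as values where none passed. The third named 14 genes of the Hedgehog pathway, osteoblasts and collagen in every case. In the knockdown comparison Top2a, Mki67, Pcna, Mcm7, Ifit3, Isg15, Stat1 and Foxd2 lie outside these rules and were chosen after their values were seen. The lists, fixed at the same time, covered osteoblast, collagen, matrix and metalloproteinase genes, the Hedgehog, Wnt, BMP and TGF-beta pathways, markers of other cell types (adipocyte, chondrocyte, stromal progenitor, smooth muscle, tendon, leukocyte, osteoclast, endothelial, epithelial), cell cycle, interferon, cytokine, NK cell ligand and niche factor genes, stress, hypoxia, glucocorticoid, cholesterol and immediate early genes, ribosomal proteins and mitochondrial transcripts. Each list is described by its members past the threshold over all genes, the number adjusted over the list alone, and the percentile of its median fold change among 10000 random lists matched on mean expression in 20 bins. That percentile describes these libraries and is not a test across replicates. Genes with near-identical copies or shared exons (Bglap and Bglap2, the Oas1, H2-Q, Ifi200-type and Raet1 genes, Rps3a2, Gm4759, Pcdhgb8) are uncertain, since reads may be split between copies, and antisense or overlapping genes may share reads.

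Counts of genes that differed by at least 2-fold in both knockdown libraries were set beside 100 simulated draws of unchanged groups against 1 shared control. The draws used edgeR's trend of dispersion with expression (common value 0.0392). The procedure was tested on simulated counts of the same 14918 genes in 3 draws of 200 changed genes. The changed genes were drawn only from those with a mean of at least 50 recovered reads, so the recovered shares do not cover genes with fewer reads. In the knockdown contrast limma recovered 23.3% of genes changed 2-fold and 93.3% of those changed 4-fold, and 7.25% of its calls were unchanged genes. In the contrast of control osteoblasts with MSC the shares were 25.3%, 90.7% and 10.8%. In both simulations genes of like expression were given the same dispersion. The recovered shares thus do not apply to genes with a wider spread of their own, such as the interferon-stimulated genes. Alternatives tried were other scalings, filters, pseudocounts and tools, other sets of libraries in the fit, and each knockdown library left out. Planned scaling and filter alternatives were run in the limma fit; comparing the per-sample files with the series table gave no separate setting, since they are copies of its columns.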

Results

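The data comprised 4 RNA-seq libraries: MSC, osteoblasts differentiated from MSC with conditioned medium of control MCF7 (control medium below), and osteoblasts differentiated with conditioned medium of SCUBE2-deficient MCF7 (KD1 and KD2 medium, n = 2). The recovered depth was between 20782984 and 25074727 reads per library, and 14918 genes were tested. The series' question is the part SCUBE2 of luminal breast cancer cells plays in osteoblastic niches of bone metastasis, which sets 2 comparisons: control osteoblasts against MSC, and knockdown medium against control medium. The targeted gene was knocked down in human MCF7 and its level there was not measured in these libraries. Mouse Scube2 itself was at 0.155 CPM in MSC, 0.764 with control medium and 0.952 ± 0.25 (SD, n = 2) with knockdown medium. Shh, a Hedgehog ligand, had no read in any of the 4 libraries, and 3 reads, the limit that a count of 0 allows, correspond to between 0.116 and 0.147 CPM.

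Osteoblasts with control medium differed from MSC in genes of bone matrix, hormone response, metabolism and proliferation. By limma, 1632 genes were higher and 1879 lower in control osteoblasts (adjusted p threshold 0.05). Of these, 1627 and 1879 lay on the same side of MSC in all 3 osteoblast libraries. That is no replication, since all 3 differences subtract the same MSC library and the control library served to pick the genes. Collagen chains stood among the higher genes: of 35 tested, 14 rose and 2 fell (18 passed when adjusted over the list alone), and the median of 1.33 lay at percentile 100 of random lists. Col3a1 rose from 276 to 3330 CPM (log2 fold change 3.59, SE 0.188, adjusted p = 0.00704). Col6a2 rose by 3.10 and Col6a1 by 2.76 on the log2 scale. The bone collagen chains Col1a1 and Col1a2, at 16352 and 13008 CPM in MSC, rose by 1.59 (SE 0.316, adjusted p = 0.032) and 1.48 (SE 0.296, adjusted p = 0.0322), and Col1a1 then took 4.73% of all reads. Col2a1, the cartilage collagen, fell from 19.5 CPM to 0.127 CPM (3 reads), and Col10a1 fell by 2.01 on the log2 scale.

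Of 21 osteoblast and mineralisation genes tested, 6 rose and none fell, also 6 when adjusted over the list alone (median 0.64, percentile 99.95). Alpl, the alkaline phosphatase of mineralising cells, rose from 41.9 to 406 CPM (log2 fold change 3.25, SE 0.434, adjusted p = 0.0386). Omd, which encodes osteomodulin, rose by 4.82 on the log2 scale, Smpd3 by 2.08 and Mef2c by 1.92. The osteoblast transcription factors Runx2 (82.2 and 126 CPM, adjusted p = 0.0777) and Sp7 (15.6 and 20.7 CPM, adjusted p = 0.865) did not pass, nor did Spp1 (1610 and 1881 CPM). Ibsp, encoding bone sialoprotein, had no read in MSC and 14.9 CPM in control osteoblasts, at least 128-fold higher, but its adjusted p was 0.351. Bglap, the gene of osteocalcin, stayed below 0.14 CPM in all 4 libraries.

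Other matrix genes were also higher. Among proteoglycan and matricellular genes 8 of 26 rose (9 over the list alone) and none fell, led by Aspn (asporin, 1.28 to 304 CPM, log2 fold change 7.06, SE 0.533, adjusted p = 0.0274) Ogn (log2 fold change 3.23), Mfap5 (1.88) and Dcn (decorin, 1.73). Of 16 metalloproteinase and inhibitor genes 6 rose and 1 fell (7 and 1 over the list alone): Adamts1 rose by 2.37, Mmp2 by 1.87 and Mmp16 by 1.74, and Timp3 fell by 1.99 on the log2 scale. Niche factors rose in 5 of 16 cases (5 over the list alone). Bmp2 had 1 read in MSC and 20.2 CPM with control medium (ratio 522, 95% interval 93.2 to 20660). Gas6 rose from 32.5 to 454 CPM, Jag1 by 2.38 and Igf1 by 1.27 on the log2 scale. Collagen-processing genes moved both ways, 5 up and 4 down of 28 (7 and 5 over the list alone), and included Loxl2 (log2 fold change −2.27), P4ha2 (−1.94), Loxl3 (−1.19) and Adamts2 (1.53). Glucocorticoid response genes rose in 6 of 15 cases and fell in 1 (the same numbers over the list alone). Zbtb16 had no read in MSC and 18.8 CPM in control osteoblasts (at least 162-fold higher), Tsc22d3 rose by 2.60 on the log2 scale and Klf15 by 2.53. Cdkn1a, a cell-cycle inhibitor, was the member that fell, by 2.29.

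The lists with the lowest medians were those of glycolysis and proliferation. Hypoxia and glycolysis genes fell in 17 of 20 cases (17 over the list alone, median −2.24, percentile 0). Ldha, lactate dehydrogenase, fell from 2130 to 241 CPM (log2 fold change −3.14, SE 0.148, adjusted p = 0.00674), and Pgk1 fell by 3.00, Egln3 by 3.07 and Bnip3 by 2.97. All 25 cell cycle genes fell (25 over the list alone, median −1.79), with Aurka at 86.5 and 11.2 CPM, Plk1 at 109 and 17.2 CPM, Bub1 at 68.0 and 11.3 CPM and Rrm2 at 162 and 28.9 CPM. BMP and TGF-beta targets fell in 6 of 17 cases and rose in 2 (7 and 3 over the list alone); Atoh8 (log2 fold change −2.82), Id1 (−2.34) and Id2 (−1.63) fell and Id4 (1.88) rose. Smooth muscle genes fell in 3 of 9 cases (3 over the list alone), namely Actg2 (log2 fold change −2.71), Tagln (−2.18) and Acta2 (−1.22). Cholesterol synthesis genes fell in 5 of 18 cases (6 over the list alone), among them Fdps (−1.19), Fdft1 (−0.90), Hmgcr (−0.87) and Sqle (−0.76). Ribosomal protein genes fell in 14 of 79 cases (1 over the list alone), among them Rps27l (−1.67), Rps24 (−0.91), Rpl15 (−0.83) and Rpl35 (−0.83). Of 6 Hedgehog targets tested, Ptch1 alone passed and fell from 122 to 23.2 CPM (log2 fold change −2.35, SE 0.135, adjusted p = 0.00775; 1 over the list alone). Gli1, the other textbook target, was at 0.737 CPM (19 reads) in MSC and 0.34 CPM (8 reads) with control medium.

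The remaining lists are given next. The values in brackets in this paragraph are log2 fold changes. Of 16 Hedgehog components Cdon (0.75) and Evc2 (0.74) rose and Scube1 (−2.23) fell (6 and 1 over the list alone). DESeq2 and edgeR called no component lower. Stress response genes rose in 6 of 20 cases (6 up and 4 down over the list alone), among them Aldh1l2 (1.21), Atf3 (1.12), Chac1 (1.004) and Trib3 (0.83). Of 12 immediate early genes Nr4a1 (1.90) and Fosb (1.83) rose and Fosl1 (−3.16) fell, and of 21 NK cell ligand genes Pvr (−1.40) and Raet1e (−1.12) fell. Of 19 Wnt genes Lgr6 (−2.70), Rnf43 (−2.17) and Notum (−1.13) fell (2 over the list alone). Of 18 stromal progenitor markers Pdgfrb (1.30) rose, and Cd44 (−1.39) and Lepr (−1.19) fell. Of 9 adipocyte genes Plin4 (2.27) and Cebpa (2.204) rose, and Dgat2 (−1.19) and Acsl1 (−0.86) fell. By DESeq2 and edgeR no adipocyte gene was called lower. Of 8 chondrocyte genes Comp (1.80) and Sox9 (1.69) rose. Of 5 osteoclast genes Ctsk (0.65) rose and Tnfrsf11a (−1.91) fell (2 and 1 over the list alone). Of 4 epithelial markers Esr1 (1.33) rose and Krt19 (−4.61) fell (2 and 1 over the list alone), and of 15 mitochondrial transcripts mt-Rnr1 (1.11) rose. None of the 4 tendon, 8 leukocyte, 4 endothelial, 23 interferon-stimulated and 19 cytokine genes passed. Where no second number is given, adjustment over the list alone gave the same numbers. Among single genes past the threshold with a mean log2(CPM + 1) of at least 2, Fam180a (5.72), Sned1 (5.23), Enpp2 (5.07, the lysophosphatidic acid-producing enzyme autotaxin), Nov (5.18) and Enpep (5.42) were among the 10 largest rises, and Hif3a had 1 read in MSC and 47.8 CPM with control medium (ratio 1232, 95% interval 221 to 48710). Gm4759 (6.02) and Ctla2a (4.84) rose too. The largest falls among these genes were those of Ak4 (−3.95), Elfn1 (−3.71), Rasl11a (−3.68), Slc6a17 (−3.68), Cemip (−3.62), Elovl7 (−3.48), Gm2115 (−3.47), Fam162a (−3.45), Il1rl1 (−3.37) and Sox11 (−3.21). This comparison sets 1 library against 1 and takes its spread from the knockdown pair, and osteogenic medium, time and tumour-conditioned medium changed together. With every gene of at least 1 read in the limma fit no gene passed, whereas edgeR's quasi-likelihood test on the same genes called 1808 higher and 1941 lower.

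**Figure D1:**
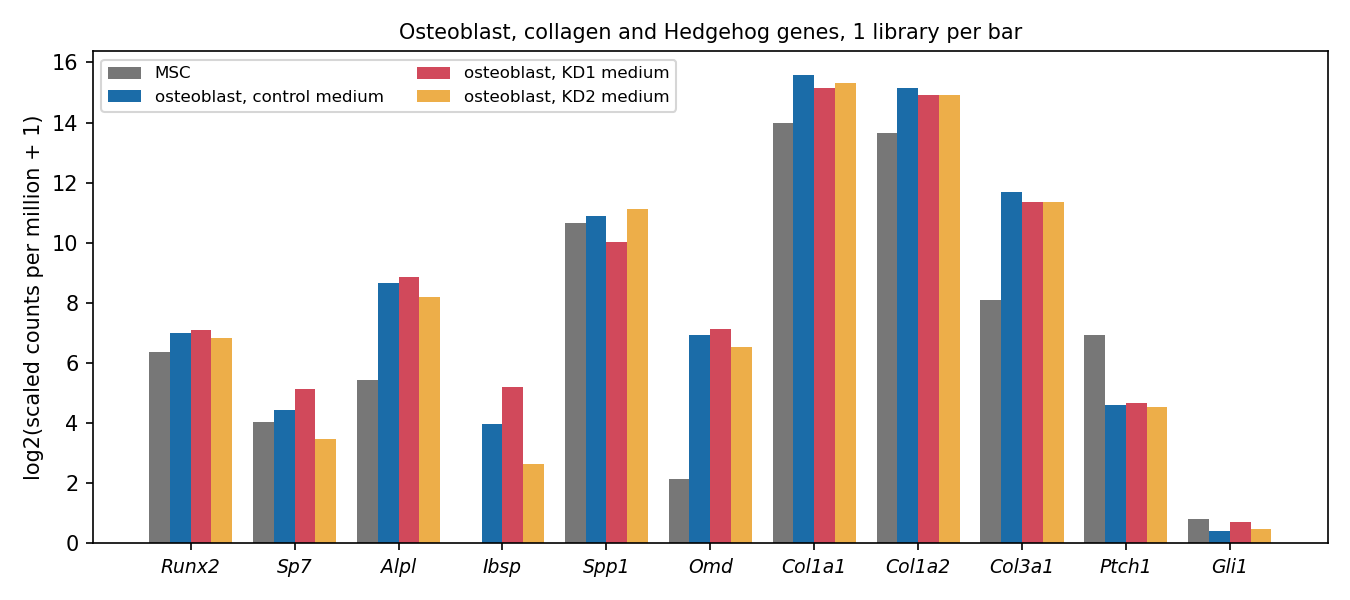
Bars give log2(CPM + 1) of osteoblast, collagen and Hedgehog genes in the 4 libraries, 1 library per bar and no error bars. Alpl and Col3a1 stand above MSC in all 3 osteoblast libraries, Ptch1 stands below MSC in all 3, and Ibsp and Sp7 with KD1 and KD2 medium lie on opposite sides of control medium.

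The second comparison asked what osteoblasts lose or gain when the tumour cells that conditioned the medium lack SCUBE2. Cell cycle genes were lower with both knockdown media. All 25 listed genes, which run from the replication helicase to mitotic kinases, were below control in KD1 and in KD2, with a median log2 difference of −1.10 (−1.14 in KD1 and −1.23 in KD2) at percentile 0 of random lists. Of all 14918 genes 33% were below control in both libraries and 35.3% above in both, the shares to set beside such counts for each list. Adjusted over the list alone, 23 of the 25 fell by limma (smallest adjusted p = 0.000793), and over all genes none passed. Plk1, a mitotic kinase, was at 17.2 CPM with control medium and 4.63 ± 0.0257 (SD, n = 2) with knockdown medium (log2 fold change −1.69, SE 0.14; adjusted p = 0.172 over all genes). Ccna2 was at 34.8 and 11.5 ± 0.367 (SD, n = 2) CPM, Top2a at 117 and 43.9 ± 1.22 (SD, n = 2) CPM, and Mki67 at 88.4 and 31.2 ± 3.22 (SD, n = 2) CPM. Pcna (91.3 CPM, then 77.6 and 81.4) and Mcm7 (44.0 CPM, then 41.4 and 31.7) were the members that did not pass.

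Of the 30 lists, that of interferon-stimulated genes had the median furthest from control. All 23 were below control in both knockdown libraries, with a median of −2.17 (−3.26 in KD1 and −1.17 in KD2, percentile 0), and 15 of them were at least 2-fold lower in both. None passed over all genes or over the list alone (smallest adjusted p = 0.366), with KD1 and KD2 far apart. Ifit3 was at 1269 CPM with control medium, 71.5 with KD1 and 452 with KD2 medium. Irf7, the transcription factor that amplifies interferon responses, was at 230, 16.4 and 65.2 CPM, Isg15 at 451, 44.0 and 184 CPM, and the chemokine gene Cxcl10 at 114, 2.78 and 33.9 CPM. Stat1 was at 650, 123 and 340 CPM. In MSC, Irf7 was at 266 and Isg15 at 477 CPM, and the median difference of control osteoblasts from MSC was 0.30. Summed over 16 leukocyte markers, leaving out the class II genes, expression was 16.5 CPM with control medium, 12.3 with KD1 and 19.4 with KD2.

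**Figure D2:**
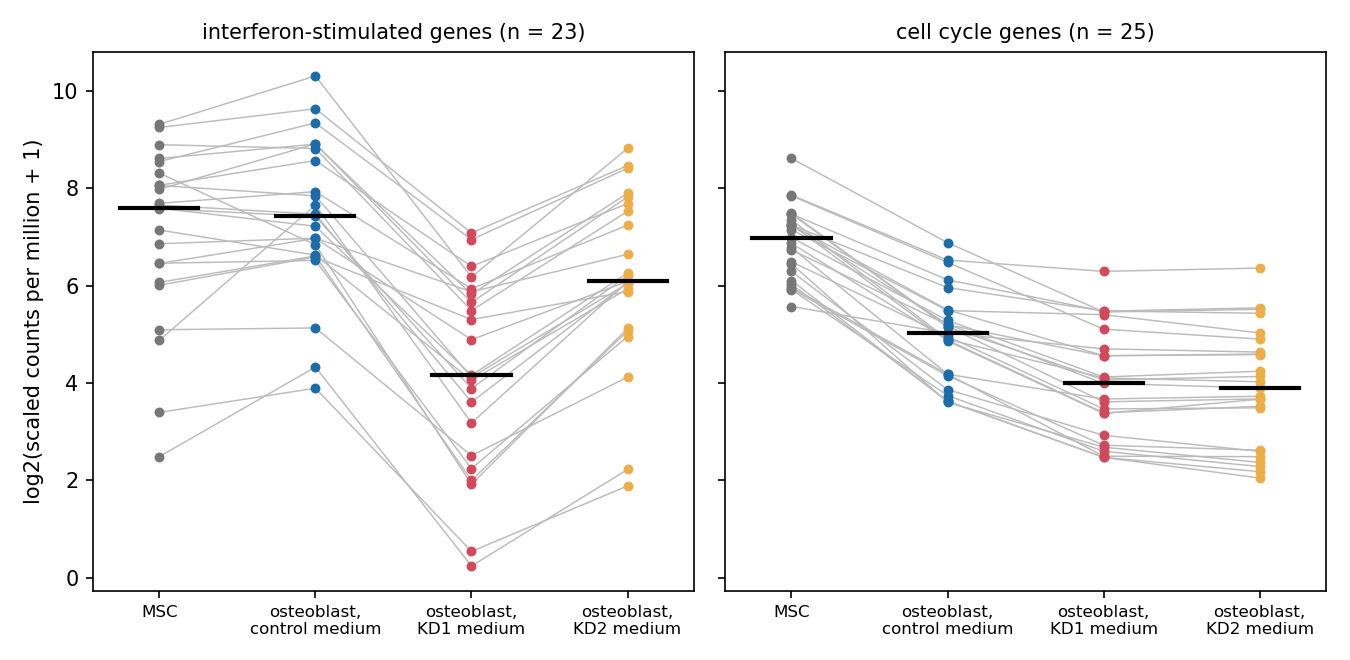
Each point is 1 gene, as log2(CPM + 1), in each of the 4 libraries, grey lines join the same gene and black bars are list medians. The medians of the 23 interferon-stimulated genes' differences from control are −3.26 with KD1 and −1.17 with KD2 medium, and those of the 25 cell cycle genes are −1.14 and −1.23.

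Among genes with a mean log2(CPM + 1) of at least 2, none of them past the threshold, those furthest below control by the smaller of the 2 libraries' differences were Ifi213 (15.9 CPM, then 0.137 and 1.96), Oas1g (16.4, then 0.501 and 2.85), Ifi206 (58.7, then 1.41 and 12.7), Oas3 (19.1, then 0.182 and 3.68), H2-Q6 (23.7, then 1.41 and 4.91), Mx1 (13.9, then 0.456 and 2.70), Tgtp1 (22.9, then 0.319 and 5.45), Irf7, Oasl1 (9.97, then 0.137 and 2.16) and the lipocalin gene Apod (646, then 98.1 and 186 CPM). Above control in both, ranked in the same way, Ifi27 stood first, at 52.8 CPM with control medium and 171 ± 38.4 (SD, n = 2) with knockdown medium (log2 fold change 1.66, SE 0.239, adjusted p = 0.517), a gene outside the interferon-stimulated list. It was followed by Pcdhgb8 (0.90), Dusp5 (0.80), Cdk5r1 (1.21), Ypel1 (0.84), Fam210b (0.75), Elovl7 (0.72), Aif1l (0.72), Gfra1 (0.79) and Morn2 (0.72), given as log2 fold changes, none past the threshold.

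Cytokine and chemokine genes differed between the knockdown libraries. Their 19 tested members had a median of −2.28 with KD1 and 0.08 with KD2 (−1.02 for the pair), 7 were lower in both, and none passed over all genes or over the list alone. Ccl2, a monocyte chemoattractant, was at 222 CPM with control medium, 9.16 with KD1 and 225 with KD2, and Cxcl5 at 285, 12.03 and 315 CPM. Whether KD1 and KD2 differ could not be tested with 1 library of each. NK cell ligand and checkpoint genes had a median of −0.38 (−0.64 and −0.13; percentile 0), with 10 of 21 lower in both. The MHC class I genes H2-K1 (1623, then 408 and 954 CPM) and H2-D1 (2372, then 669 and 1452 CPM) were furthest from control, and none of the 21 passed over all genes or over the list alone.

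Collagen genes were slightly lower and osteoblast genes lay on both sides of control. Of 35 collagen chains, 18 were below control in both knockdown libraries and 6 above in both, with a median of −0.18 (−0.19 and −0.16; percentile 0), and none passed over all genes or over the list alone (smallest adjusted p = 0.505). Col1a1 was at 49185 CPM with control medium and 38751 ± 2831 (SD, n = 2) with knockdown medium (log2 fold change −0.35, SE 0.273, adjusted p = 0.973). Col1a2 (−0.24, SE 0.256) and Col3a1 (−0.34, SE 0.163) gave similar values. Col11a2 had a log2 fold change of 1.10 (SE 1.14). Collagen-processing genes had a median of −0.20 (−0.22 with KD1 and −0.06 with KD2), with 18 of 28 lower in both, and proteoglycan and matricellular genes one of −0.17 (−0.08 and −0.19), with 10 of 26 lower in both. Of 21 osteoblast genes, 3 were lower and 5 higher in both libraries, and the median was −0.03 (0.18 with KD1, −0.15 with KD2, and 0.014 for the pair with library totals alone; percentile 23.5). Ibsp was at 14.9 CPM with control, 35.8 with KD1 and 5.2 with KD2 medium, Sp7 at 20.7, 34.1 and 10.2 CPM, and Alpl at 406, 463 and 289 CPM. Runx2 was at 126 and 124 ± 17.5 (SD, n = 2) CPM, and Spp1 at 1881 and 1634 ± 828 (SD, n = 2) CPM.

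Of 6 Hedgehog targets tested 3 were above control with both knockdown media and none below with both. The 3 were Foxd1 (14.6 CPM, then 22.8 and 18.2; log2 fold change 0.45, SE 0.182, adjusted p = 0.973), Foxd2 (1.40 CPM, then 2.19 and 2.21; adjusted p = 0.973), which was chosen after its values were seen, and Gli1. Ptch1 was at 23.2 CPM with control and 23.3 ± 1.36 (SD, n = 2) with knockdown medium (log2 fold change 0.01, SE 0.117, adjusted p = 0.995). Gli1 had 8 reads with control medium and 14 and 8 reads with knockdown media, too few to show a difference of this size, and Hhip had 2 reads in KD1 and none in the other 3 libraries. The targets had a median of 0.09 (0.18 with KD1 and 0.12 with KD2; percentile 82.5), the 16 components one of −0.04 (−0.02 and −0.045, and 0.01 with library totals alone), and none of either passed over all genes or over the list alone.

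Transcripts of the translation and respiration machinery were higher with both knockdown media. Of 79 ribosomal protein genes 75 were above control in both (77 with library totals alone, median 0.27, percentile 100; none passed over all genes or over the list alone), as were all 15 mitochondrial transcripts under either scaling (median 0.35), of which mt-Nd4l passed adjusted over the list alone (log2 fold change 0.63, SE 0.108, adjusted p = 0.0463). Their shares of reads are signs of RNA composition. These shares were higher with both knockdown media, where the medians of the interferon, cell cycle and collagen lists were lower, and no link was tested. Ribosomal protein genes took 4.09% of reads with control medium, 5.48% with KD1, 4.75% with KD2 and 6.13% in MSC. Mitochondrial transcripts took 2.38%, 3.35%, 2.88% and 2.75%. Cholesterol synthesis genes were above control in both libraries in 11 of 18 cases and below in none (median 0.21, with 0.065 in KD1 and 0.37 in KD2; percentile 100), with Insig1 at 65.8, 77.9 and 108 CPM.

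In the other lists none passed by limma over all genes or over the list alone, and DESeq2 called Ly6a alone. Several of their medians came from 1 knockdown library. That of niche factors was −0.19 (percentile 0.06; −0.30 with KD1 and 0.034 with KD2), that of metalloproteinases −0.12 (percentile 1.53; −0.315 and 0.037), and that of immediate early genes 0.16 (percentile 99.79; −0.20 and 0.54, with 7 of 12 lower in KD1 and higher in KD2). For Wnt genes it was −0.13 (percentile 2.10; −0.017 and −0.13). The medians of the next lists, with their percentiles among random lists, were 0.07 (94.3) for hypoxia and glycolysis, 0.07 (89.0) for BMP and TGF-beta targets, 0.03 (80.8) for stress response and 0.02 (67.8) for glucocorticoid response genes. For the cell type markers they were 0.05 (64.0) for adipocytes, 0.06 (68.9) for chondrocytes, −0.01 (37.7) for stromal progenitors, −0.09 (10.7) for smooth muscle, −0.07 (22.6) for tendon, −0.06 (29.4) for leukocytes, 0.05 (62.7) for osteoclasts, −0.11 (21.7) for endothelium and −0.02 (41.8) for epithelium. Of these, KD1 and KD2 gave medians on opposite sides of control for BMP and TGF-beta targets (−0.011 and 0.058), glucocorticoid response genes (−0.09 and 0.13), stromal progenitors (0.094 and −0.22), smooth muscle (0.017 and −0.10), leukocytes (−0.32 and 0.081) and epithelium (0.094 and −0.10). On 1 side of control, but more than 1.5 times away from the pooled median with a library left out, were hypoxia and glycolysis (0.006 and 0.125), stress response (0.14 and 0.004), adipocytes (0.021 and 0.081), chondrocytes (0.062 and 0.023) and osteoclasts (0.073 and 0.15). Library totals alone turned the medians of stromal progenitors (0.015) and epithelium (0.006). Mmp13, a collagenase, was at 307 CPM with control, 48.8 with KD1 and 375 with KD2 medium. Ly6a, a stromal progenitor marker, was at 445 CPM with control medium and 169 ± 67 (SD, n = 2) with knockdown medium (log2 fold change −1.45, SE 0.479; adjusted p = 0.973 by limma and 0.0392 by DESeq2).

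Over all 14918 genes limma called none in this comparison at an adjusted p of 0.05 (smallest 0.172), with 544 at an unadjusted p under 0.05 where chance alone gives 746. edgeR's quasi-likelihood test on the recovered reads also called none, with 544 at an unadjusted p under 0.05 (smallest adjusted p = 0.0829), but on every gene with at least 1 read it called 36 lower. DESeq2's Wald test gave no adjusted p for 4917 of the genes, which it thus could not call. It called 71, of which 70 were lower and 1, Ifi27, higher (adjusted p = 3.25e-05). Of the lower ones 15 were in the cell cycle list and none in the interferon list. Outside that list, further genes of cell division such as Kif20a, Tpx2, Cenpf, Aspm and Espl1 were also called lower. Others, such as Gfra2 and Slfn9, are not cell division genes. These 7 genes were named after their values were seen. Counted by size, 172 genes were at least 2-fold lower in both knockdown libraries and 4 at least 2-fold higher. The 4, chosen after their values were seen, were Ifi27, Gm10401 and Gm21742, both with no read in the control library, and a gene without a symbol. In simulated unchanged groups against 1 shared control the means were 6.34 (highest 14) and 10.8 (highest 21), and independent lists would share 7 and 0.0692. The numbers of lower and higher genes were 205 and 14 with a pseudocount of 0.5 (simulated means 19.5 and 29.3) and 78 and 1 with a pseudocount of 5 (1.18 and 2.99). At 1.5-fold they were 385 and 53 (simulated means 199 and 238), and at 3-fold 25 and 0 (0.02 and 0.01). The simulation gave genes of like expression the same dispersion, and at 1.5-fold it had more higher genes than were seen. Its means are thus no chance level for genes that vary more or less than that, such as the interferon-stimulated genes. Of the 172 lower genes, 14 were in the cell cycle list and 15 in the interferon list. KD1 medium alone gave 481 lower and 86 higher genes, KD2 alone 217 and 12. Across genes, which are not independent replicates, the differences of KD1 and of KD2 from control had a Pearson correlation of 0.553 against 0.498 in the simulation, and a covariance of 0.0737 against 0.0666. The single control library enters both differences, so part of what they have in common may come from it.

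**Figure D3:**
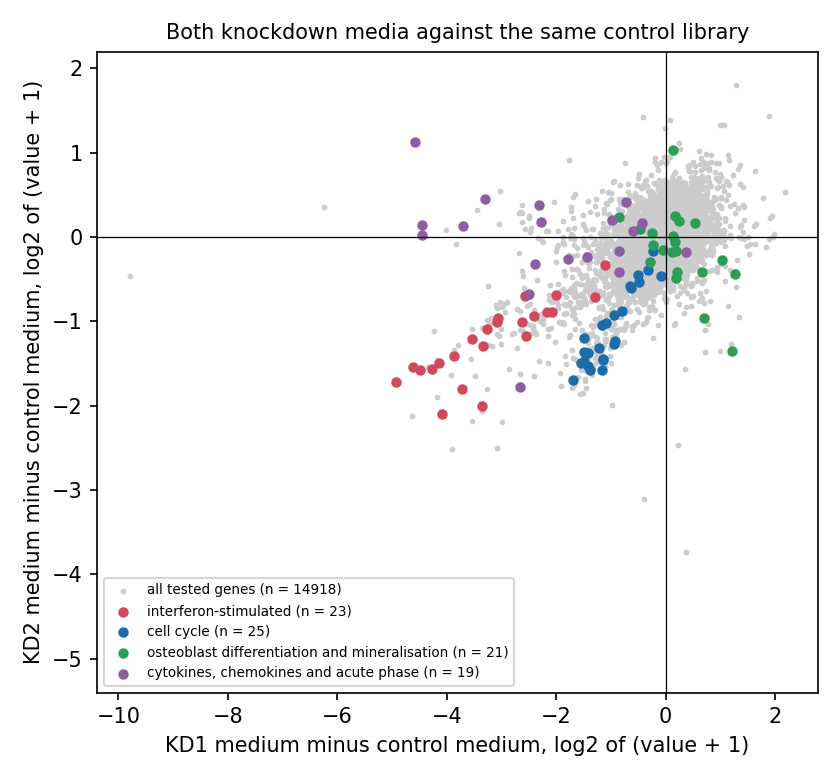
Each point is 1 gene, with its log2(CPM + 1) difference from the single control library in KD1 medium on the horizontal axis and in KD2 medium on the vertical axis. Cell cycle genes lie near the diagonal (medians −1.14 and −1.23), interferon-stimulated genes below 0 on both axes and further in KD1 (−3.26 and −1.17), and cytokine genes have medians of −2.28 and 0.08.

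Genes that separate osteoblasts from MSC were followed in libraries not used to pick them. For 243 genes at least 4-fold higher with KD2 medium than in MSC, the median log2 difference of KD1 from control medium was −0.14, and for 252 genes picked with KD1 the median difference of KD2 was −0.06. For 350 genes at least 4-fold lower with KD2 medium than in MSC the median difference of KD1 was −0.68, and for 449 picked with KD1 that of KD2 was −0.63. The libraries used for picking also received knockdown medium, so genes lower with either knockdown medium enter the lower set more readily. With a 2-fold limit the medians were −0.018 and 0.019 for the higher sets, the second on the other side of control, and −0.18 and −0.17 for the lower sets. With an 8-fold limit they were −0.23 and −0.22, and −1.14 and −1.065. With a pseudocount of 5 those of the higher sets were −0.21 and −0.10, and with 0.5 they were −0.087 and −0.058.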

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

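The list-alone settings, the pseudocounts in the 2 tests and edgeR on every gene with at least 1 read were chosen after the results were seen; edgeR's test itself was planned for counts and became an alternative, on recovered reads, once the values were seen not to be counts. In the knockdown comparison the count of genes past the threshold was 0 in each direction under limma with the other scalings, filters and pseudocounts, with limma-voom, without robust moderation and with the 3 osteoblast libraries alone. DESeq2's Wald test gave 1 higher and 70 lower genes, and edgeR's quasi-likelihood test on every gene with at least 1 read gave 36 lower. Genes of the cell cycle list past the threshold over the list alone numbered between 16 and 23 under the settings tried, and interferon-stimulated genes 0 in each. Against MSC, limma gave 0 higher and 0 lower genes with every gene of at least 1 count (the cause was not tested), DESeq2 gave 1081 lower genes, and all 3 osteoblast libraries as 1 group gave 2792 higher and 2975 lower, with ranges from 1275 to 3458 and from 1326 to 3446 when 1 osteoblast library was left out; the lowest of these are without KD2 and the highest without KD1. Genes at least 2-fold lower in both knockdown libraries numbered 78 with a pseudocount of 5, 385 at 1.5-fold and 25 at 3-fold, and those higher numbered 14 with a pseudocount of 0.5, 1 with a pseudocount of 5 or a mean CPM of at least 5, 53 at 1.5-fold and 0 at 3-fold; with 1 knockdown library left out the ranges were 217 to 481 and 12 to 86. Leaving out 1 knockdown library put the list medians between −1.23 and −1.14 for cell cycle, −3.26 and −1.17 for interferon-stimulated, −2.28 and 0.08 for cytokine, −0.15 and 0.18 for osteoblast, −0.19 and −0.16 for collagen, 0.12 and 0.18 for Hedgehog target and 0.19 and 0.34 for ribosomal protein genes. Library totals alone moved the collagen median to −0.13 and turned those of osteoblast genes (0.014), Hedgehog components (0.01), stromal progenitors (0.015) and epithelium (0.006). The median of all genes moved by 0.05 or less in the knockdown comparison and by 0.08 or less against MSC. For genes picked against MSC, the medians of the higher sets were −0.087 and −0.058 (pseudocount 0.5), −0.21 and −0.10 (pseudocount 5), −0.018 and 0.019 (2-fold) and −0.23 and −0.22 (8-fold). Those of the lower sets were −0.72 and −0.65 (pseudocount 0.5), −0.67 and −0.69 (pseudocount 5), −0.18 and −0.17 (2-fold) and −1.14 and −1.065 (8-fold).

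Among the genes named by rule, with both knockdown libraries in the fit, direction turned for Nfatc1, Runx2, Sp7 and Ibsp in the knockdown comparison. None of them was past the threshold there. Nfatc1 (0.039) and Runx2 (0.014) turned with library totals alone, and Sp7 with DESeq2 (0.093) and edgeR (0.096, and 0.099 on every gene). Ibsp turned with DESeq2 (0.46), edgeR (0.46, and 0.47 on every gene) and a pseudocount of 5 (0.039). Saa3, named after its values were seen, turned with DESeq2 (0.15) and edgeR (0.16, also on every gene). Against MSC it turned, with osteoblast libraries as 1 group, for Cd74 (−0.63, and from −1.02 to −1.01 with 1 library left out), Flt1 (−0.14, and −0.41 to −0.17), Oas3 (−0.22, and −1.25 to −0.20), Oas2 (−0.25), Sp7 (−0.092) and Spp1 (−0.197 to −0.078), of which none had passed. No paired analysis was possible because the control and MSC groups hold 1 library each. With 1 knockdown library left out no residual degree of freedom remains, so only values are given, and folds against MSC then stay as they are. Direction in the knockdown comparison then turned for further named genes. With KD2 alone, for example, Ccl2 (0.02), Cxcl5 (0.145) and Mmp13 (0.29) lay above control. For the pair their log2 fold changes were −2.22, −2.15 and −1.17. At this depth a gene with no read in a library is limited to between 0.116 and 0.147 CPM, so Shh, Hhip and Bglap, with 3 reads or fewer in each library, cannot be compared between media.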

Other observations

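Genes of antigen presentation were lower with both knockdown media. All gene families, genes and tests in this part were chosen after the results were seen, and none of the families was tested across replicates. Of 11 genes of peptide processing (immunoproteasome subunits, the Tap transporters, B2m and their regulator Nlrc5) all were below control in both libraries, with a median log2 difference of −1.09 (−1.71 with KD1 and −0.58 with KD2). Of 14 MHC class I heavy chain genes 13 were lower in both, with a median of −1.26 (−1.73 and −0.74), and all 10 guanylate-binding protein genes were lower in both, with a median of −2.04 (−2.79 and −1.12). Of random lists matched on expression 95% had medians between −0.15 and 0.13 for a family of this last size. That range is no test of these families, since they were picked after the results were seen. Some of their genes were already in a fixed list: 1 of the 11 peptide processing, 3 of the 14 MHC class I and 2 of the 10 guanylate-binding protein genes. The receptors and signalling genes of the interferon pathway, 3 of them in a fixed list, had a median of −0.24 (−0.58 with KD1 and −0.001 with KD2), with 6 of 13 lower in both. Centromere protein genes, none in a fixed list, were lower in both in 16 of 19 cases (median −0.61), and DESeq2 called 3 of them lower. It gave no adjusted p for several others, such as Cenph and Cenpp. The 38 genes with kinesin symbols included Kif1bp, which encodes a kinesin-binding protein and was higher in both. These 38 genes, 2 of them in a fixed list, went both ways: 20 were lower in both, 10 of these at least 2-fold, and 12 higher in both. Their median was −0.05 (−0.079 with KD1, −0.071 with KD2, and −0.003 with library totals alone), and DESeq2 called 7 lower and none higher. The 31 replication-dependent histone genes had a median of 0.17 (0.11 and 0.24). Many of them had few reads, for example Hist1h3e with 2 and Hist1h4k with 8 in the control library, too few to compare media. The other families looked at were nuclear complex I subunits (0.12), proteasome subunits (−0.09, with −0.12 in KD1, −0.057 in KD2 and −0.042 with library totals alone) and gamma-protocadherins (−0.07, and −0.042 with library totals alone).

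A further set of genes parted the 2 knockdown libraries. C3, the central complement component, was at 16.5 CPM in MSC, 1246 with control, 0.41 with KD1 and 906 with KD2 medium. Among genes with a mean log2(CPM + 1) of at least 2, 61 were at least 2-fold below control with KD1 medium while KD2 lay above it, and 16 were at least 2-fold above control with KD1 while KD2 lay below. Among these, acute-phase and chemokine genes included Steap4 (148 CPM with control, 0.957 with KD1 and 190 with KD2 medium), Saa3 (22.9, 0 and 51.2), Cxcl5, Ccl2, Ccl7 (156, 11.0 and 171) and Hp (174, 20.2 and 194). No test of this difference was possible with 1 library of each medium.

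The lower interferon-stimulated genes were set against 3 explanations. Leukocyte RNA in the control library is argued against, since 16 leukocyte markers were 1.04 times as high with control as with knockdown media while the interferon-stimulated genes were 3.47 times as high, and the markers summed to 0.254% of those genes. Scaling is argued against, since 1 factor per library moves all genes alike, whereas the list median minus that of all genes was −2.18 and 95% of random lists had medians between −0.08 and 0.073. A control library unlike other control cultures cannot be told apart from an effect of the medium, because there is 1 such library; the list median of the knockdown libraries minus MSC was −1.78, but MSC are another cell state. An effect of the tumour-conditioned medium stays open as a hypothesis, untested. Whether KD1 and KD2 differed through their media, cultures or libraries cannot be told with 1 library of each.

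The lower cell cycle genes were set against 3 explanations as well. A shift further from MSC of all genes alike is argued against by hypoxia and glycolysis genes, the fixed list furthest below MSC, whose median lay 1.175 above that of the cell cycle list (SD of its 20 genes 0.22, lowest −0.32). A shift of part of the genes stays open. Scaling is argued against by a list median of −1.109 relative to all genes, with 95% of random lists between −0.069 and 0.084. A control culture that cycled more than others would cannot be told apart from an effect of the medium, since the only replicate spread is that of the knockdown pair (a median difference of 0.0788 between KD1 and KD2 in this list). Fewer cycling cells with knockdown medium remain a hypothesis that more control cultures would test.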
